A study of Arabidopsis thaliana and Oryza sativa and Cucumis sativus with 30 samples.

How the data were processed

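RNA of root cells was sequenced in 30 libraries, 3 per group, from seedlings grown at 22 °C for 4 to 5 days under constant light, per the labels' protocols. Sorted cells were protoplasted, passed through fluorescence-activated sorting for GFP and prepared with TruSeq, and sieved hairs were prepared with SMART-Seq v4, per the labels' protocols. All Arabidopsis samples carry the variety label Columbia. CASAVA 1.8.2, TopHat2 2.0.3 and 2.0.9, HTSeq 0.6.1, edgeR and Cufflinks are named per the submitters' processing notes, with no role or order. The annotation of Arabidopsis was that of TAIR10, per the labels. Whether counting used strand and how it treated reads of paralogs or overlapping genes is not given in the sources used here.

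The deposited table of the rhd6 comparison holds a signal of normalized CPM, that is, counts per 1e6 reads scaled by a factor for each library, made by the authors per the file headers and the values. Every value was a whole multiple of what 1 read is worth in its library (100% within 0.01 of a read), so whole reads were recovered. The same table holds the authors' log2 fold changes and log2 mean levels, their p-values and FDR, and other columns, a likelihood ratio and a mark set where the FDR is below 0.01, per the file headers. The other 8 tables hold FPKM computed by the authors, per the file headers and the submitters' processing notes, and 2 of them a mark of expressed genes. All 6 sieved tables list only genes with a mean FPKM of 3 or more, as tested on the values. An FPKM of exactly 0 can be a failed estimate, so such genes are called listed at 0.

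Groups came from the labels. Columns of the tables carry library numbers or sample names that tie them to a group, and the labels tie the numbers to replicates for EXPA30::GFP but not for WER::GFP or COBL9::GFP. All 3 wild-type WER::GFP numbers are lower than all 3 rhd6 ones, what the numbers stand for is not given in the sources used here, and an order of processing would not be told apart from genotype. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 13.6 to 251), so none was counted as a repeat. Wild-type replicates had r of 0.967 to 0.990 and rhd6 replicates 0.903 to 0.963 across genes. The first and second principal components held 54.0% and 27.3% of the variance, and the second set library 10019 (-65.0) apart from library 10018 (36.4). The library 8955 was read least, and 1 read is worth 0.0957 there and 0.0431 in library 9483. Intervals and floors cover counting error only, and a floor is 3 reads over the group.

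The test, the filter, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The plan was edgeR's quasi-likelihood test on counts, and limma on log2 values where a table held none. The table holds normalized values, so limma 3.58.1 in R 4.3.3 was run on log2(value + 1) with an intensity trend, two-sided, for genes at 1 or more in at least 3 of the 6 libraries, with Benjamini-Hochberg adjusted p below 0.05. Fold changes on this scale understate those of low genes. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads called 665 and 1352 genes, 648 and 722 of them among the 724, and were added as alternatives after the files were seen. Lists of 159 members, 138 of them measured, were tested in 13 of 14 lists with camera at a preset correlation of 0.01. No list was called with an estimated correlation, and fry called 4 of them. All lists were written from general knowledge of root genes, and no gene stands in more than 1 list. Root hair tables were described with percentiles among 10000 random lists of the same size, Spearman correlation and overlap of the 500 highest genes, and detection by two-sided Fisher's exact test and, added after the data were seen, by a Mantel-Haenszel test over 20 classes of equal size by wild-type mean, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

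Named genes were RHD6, the 10 largest rises and falls among genes past the threshold with a mean of 5 or more and non-overlapping groups, all members of the patterning and bHLH lists, the 4 members with the smallest p in each other list (of which 3 are given for cortex and endodermis), the 10 highest genes of each Arabidopsis table and the 2 highest of every other. Members named beside them as examples were chosen after their values were seen. Gene names came from the reference annotation of TAIR10.1, in which 17555 of 17575 tested genes were matched. Since the deposited tables use TAIR10, only names, chromosome and gene order were taken from it and base positions are not used here. Rice and the other species were reported by identifier, as gene names for them were not used here.

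The steps were tested on simulated data. With 200 changed genes of 17428 in 10 simulations, limma called 10.6%, 86.6% and 98.2% of genes changed by 1, 2 and 3 on the log2 scale, and 7.78% of its calls were unchanged genes. The list test called 0 of 20 lists of unchanged genes and 1 of 1 list of changed genes. Genes were simulated as independent, while the correlation estimated in the lists ran from 0.0171 to 0.899. The simulation therefore does not show how the preset correlation performs on correlated lists. The pair count used for gene positions passed its bound in 4.0% of random sets and in 100% of sets with a planted cluster, the family test called 5 of 100 random sets, the matched detection test 14 of 200 random sets with the levels of the lowered genes and the unmatched one 62.5% of them, and the list percentile exceeded 95 in 4.5% of random lists.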

Results

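The series holds 30 RNA sequencing libraries in 10 groups of 3, which the series design describes as biological replicates. Epidermal cells of Arabidopsis roots carrying GFP under the promoter of WEREWOLF (WER) were sorted from the wild type and from the mutant rhd6, which lacks most root hairs. Root hair cells were sorted by the hair cell reporter COBL9::GFP in Arabidopsis and by EXPA30::GFP in rice. Root hairs broken off in liquid nitrogen and sieved were collected from 6 species, namely maize, cucumber, Arabidopsis, soybean, rice and tomato. The 6 WER::GFP libraries held between 10562137 reads (wild-type library 8955) and 23110648 reads (wild-type library 9483) in the 17628 listed genes. The 24 other libraries were given as FPKM, so their depth is unknown.

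The comparison of rhd6 with wild-type epidermis asks which genes differ in a mutant of RHD6, the basic helix-loop-helix (bHLH) factor that starts root hair formation. RHD6 itself (AT1G66470, chromosome 1) fell from a mean of 78.4 ± 6.09 to 1.40 ± 0.542 normalized CPM, counts per 1e6 reads scaled by the authors (SD, n = 3 each), which is 1.78% of the wild-type level (log2 fold change -5.07 ± 0.21 SE, limma adjusted p = 9.73e-05). Most changed genes were lower in the mutant, and they included 4 of 8 other hair-forming bHLH factors and 17 of 21 listed proteins of the hair wall. None of the 12 measured genes that pattern the epidermis into hair and non-hair files passed the test in limma, while DESeq2 called 2 of them. The authors' deposited test lists EGL3 among them at an FDR of 0.0332. Of 17575 genes tested, 724 passed an adjusted p of 0.05 in limma, 573 lower and 151 higher in rhd6, and the groups did not overlap for any of the 724. Non-overlap alone was met by 27.5% of tested genes, against 10% by chance. At least 2-fold changes on the log2(value + 1) scale were seen for 548 lowered and 142 raised genes, and at least 8-fold changes for 139 and 23. The authors' deposited table lists 1175 genes at an FDR below 0.05, of which 874 were lower and 301 higher, and 722 of the 724 genes are among them. At an FDR below 0.01 it lists 844 genes, of which 649 were lower and 195 higher. The count fell to 264, 222 and 239 genes without the wild-type libraries 8955, 9483 and 9489, and to 349 without the rhd6 library 9519. Those fits tested 17291, 17242, 17278 and 17341 genes, since the filter of 3 libraries at 1 or more was kept. DESeq2 on recovered reads called 1352 genes, and limma on genes with a mean of 5 or more called 431.

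The largest falls joined hair genes and genes with no listed hair role. ACLA-2, a subunit of ATP citrate lyase, fell to 0.520 ± 0.265 normalized CPM, from 6746 reads to 29 (log2 fold change -6.38 ± 0.20 SE, limma adjusted p = 4.61e-05, n = 3 each). ACLA-2 lies on chromosome 1, as RHD6 does. Lowered genes were in excess near RHD6 (49 within 500 tested genes, against 32.6 expected), so its fall is not told apart from an effect of position. CID5, a protein with a CTC-interacting domain, fell by 5.12 on the log2 scale, and NSP3, a nitrile specifier protein of glucosinolate breakdown, fell by 5.01. Among hair genes, the peroxidase gene RHS19 went from 303 ± 102 to 12.3 ± 11.4 (log2 fold change -4.85). RHS9 had a log2 fold change of -4.76, and the extensin gene EXT10 went from 502 ± 191 to 23.5 ± 22.7 (log2 fold change -4.71). RHS9 also lies on chromosome 1, nearer to RHD6 in gene order than ACLA-2, so the same limit of position holds for its fall. The pollen Ole e 1 allergen and extensin family gene AT2G47540 went from 85.8 ± 36.6 to 2.23 ± 1.54, and AT5G21080, which encodes an uncharacterized protein, fell by 4.71. AT5G19097 was read at 47.1 ± 16.4 in wild type and by 1 read in all 3 rhd6 libraries.

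Most of the largest rises were of genes with few reads in wild type. AT2G05914 and AT5G33251 had 0 reads in the 3 wild-type libraries and 2364 and 1048 reads in rhd6. Against a floor of 3 reads over the wild-type group they were at least 749-fold and 331-fold higher. AT2G15555, a non-coding RNA, rose from 0.0900 ± 0.0781 to 69.9 ± 18.1 normalized CPM (limma adjusted p = 5.71e-05, n = 3 each). AT3G28320 rose from 0.230 to 55.1. The terpene cyclase family gene AT1G70080 rose from 8.79 ± 2.59 to 181 ± 59.6, and the TIR domain gene AT1G72900 from 2.74 ± 1.25 to 65.3 ± 23.4. AT1G60020 and AT5G46670 had 1 wild-type read each and 1797 and 1077 rhd6 reads. AT5G44440, of the berberine bridge enzyme family, and AT1G63540 had 2 wild-type reads each and 1558 and 1113 rhd6 reads. The fitted log2 values of genes with so few reads depend on the pseudocount. Raised genes lay mostly on chromosomes 1, 2 and 5, which held 140 of the 151 (92.7%), against 64.6% of tested genes and 71.9% of lowered genes.

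**Figure D1:**
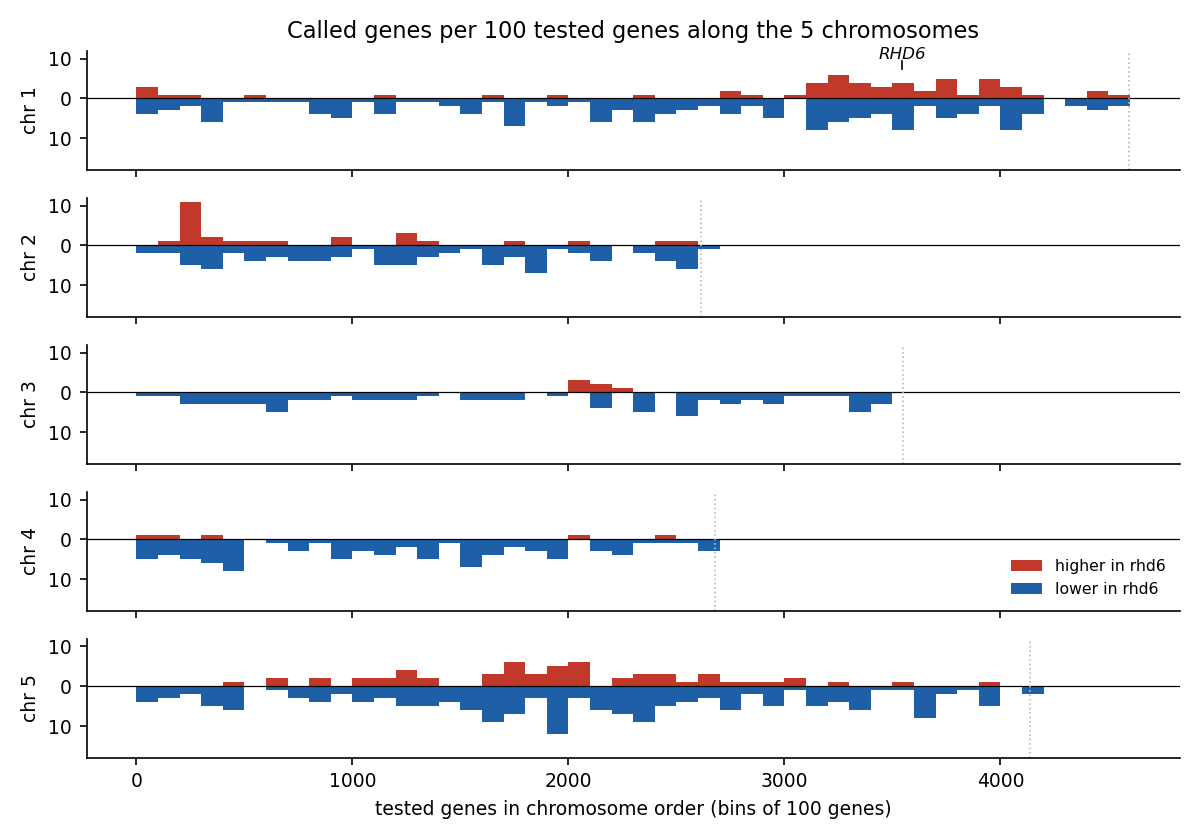
Genes past the threshold per 100 tested genes (vertical axis), in gene order along the 5 chromosomes (horizontal axis), higher in rhd6 upward and lower downward, with chromosome ends dotted. Raised genes lie around RHD6 on chromosome 1 and on chromosomes 2 and 5, while chromosomes 3 and 4 hold 6 and 5.

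**Figure D2:**
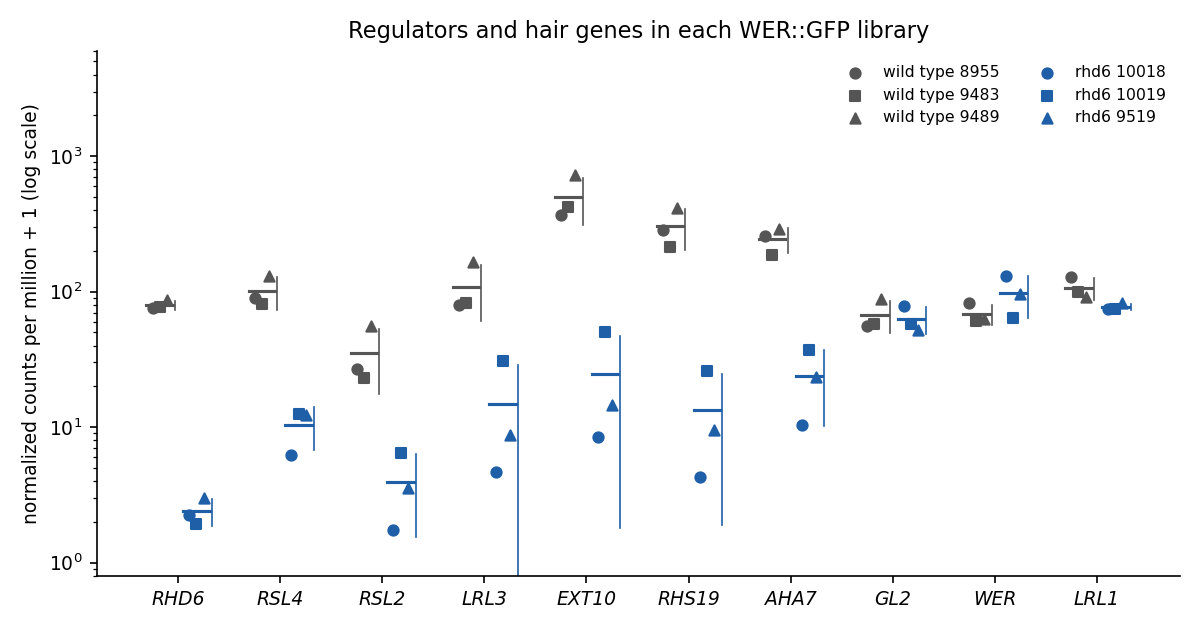
Normalized CPM plus 1 (log axis) of 10 genes in each of the 6 WER::GFP libraries. Symbols are libraries, horizontal lines are group means and vertical lines are 1 SD around the mean, and the line of LRL3 in rhd6 reaches below the axis. RHD6 lies at 78.4 in wild type and 1.40 in rhd6, while GL2 and WER overlap between the genotypes.

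Among the 8 other bHLH factors of root hairs, 4 fell and 4 did not pass the test over all genes, and 5 were lower when adjusted over the list alone, RSL5 being the added one. RSL4, which drives hair elongation, went from 99.6 ± 26.9 to 9.38 ± 3.57 normalized CPM (log2 fold change -3.31 ± 0.32, limma adjusted p = 0.00200, n = 3 each). RSL2 fell by 3.25 and LRL3 by 3.26 on the log2 scale, and RSL3 went from 161 reads to 1. RSL5 (-1.07), LRL2 (-0.62), LRL1 (-0.46) and RSL1 (-0.41), the closest relative of RHD6, did not pass in limma, and DESeq2 called RSL5 (DESeq2 log2 fold change -1.88, adjusted p = 0.0423, over 13 alternatives up to 0.379). RSL5 had an FDR of 0.0224 in the authors' deposited test. The call of RSL2 was lost without library 8955, 9489 or 9519, with limma adjusted p = 0.0553, 0.0696 and 0.0647, in a range of 5.12e-07 to 0.0696 over 14 alternatives. The call of LRL3 was lost in 5 of the 6 fits that left out a library, all but that without the rhd6 library 10019, and by edgeR. Its adjusted p ran from 0.000201 to 0.174 over 14 alternatives. RSL3 was not tested when a wild-type library was left out, and the list had 1, 2 and 1 lowered members of 7 without library 8955, 9483 or 9489. The list had 2 of 8 without library 9519, 3 by edgeR and 5 by DESeq2. As a set it was lower by camera (median log2 fold change -1.47, adjusted p = 3.95e-07, and adjusted p = 0.0862 with an estimated correlation between genes). That median was -0.83 over 7 members without library 9489, -2.64 with a pseudocount of 0.1, -2.42 by edgeR and -2.43 by DESeq2.

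Genes of the hair wall and of hair growth were lower too. Of 21 hair wall proteins, 17 were lower, 19 when adjusted over the list alone, with a median log2 fold change of -3.88 (camera adjusted p = 2.43e-20, and adjusted p = 0.236 with an estimated correlation). The 4 with the smallest p were EXT6 (-4.59), EXT14 (-4.43), EXT10 (-4.71) and the xyloglucan endotransglucosylase gene XTH13 (-3.63). LRX2 (-0.42), EXPA17 (-0.94), PRX57 (-1.54) and PRX44 (-1.93) did not pass. Of the 15 root hair specific (RHS) genes, 14 were lower, and all 15 over the list alone, with a median of -3.75 (camera adjusted p = 2.43e-20, and adjusted p = 0.236 with an estimated correlation). RHS4 went from 31.4 ± 5.21 to 1.25 ± 0.862 normalized CPM, RHS6 fell by 2.92 and RHS17 by 2.75, while RHS8 (-2.91) had a limma adjusted p = 0.0834. Of 26 genes of hair initiation and tip growth, 13 were lower and 13 did not pass, against 19 lower and 1 higher (ROP6, 0.65) over the list alone, with a median of -1.43 (camera adjusted p = 7.12e-14, and adjusted p = 0.264 with an estimated correlation). AHA7, a proton pump, went from 242 ± 52.2 to 22.7 ± 13.5, and the kinesin gene MRH2, the kinase gene IRE and the ROP activator ROPGEF3 fell by 3.19, 3.70 and 1.78. The actin gene ACT7 (0.26) and the receptor kinase gene FER (-0.27), used by most cells, did not pass. The count of lowered wall proteins was 5, 6, 4 and 5 of 21 without library 8955, 9483, 9489 or 9519, 11 by edgeR and 19 by DESeq2. Without the same libraries, that of RHS genes was 8, 9, 8 and 9, of 14, 14, 14 and 15 measured, and that of tip growth genes 6, 4, 4 and 6. The counts of RHS and tip growth genes were 11 and 12 by edgeR and 15 and 16 by DESeq2, while all 3 lists stayed lower by camera. In the rhd6 library 10019 the 48 lowered genes of the 4 hair lists were read at a median 16.7% of the wild-type mean, against 2.28% in library 10018 and 5.44% in library 9519.

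**Figure D3:**
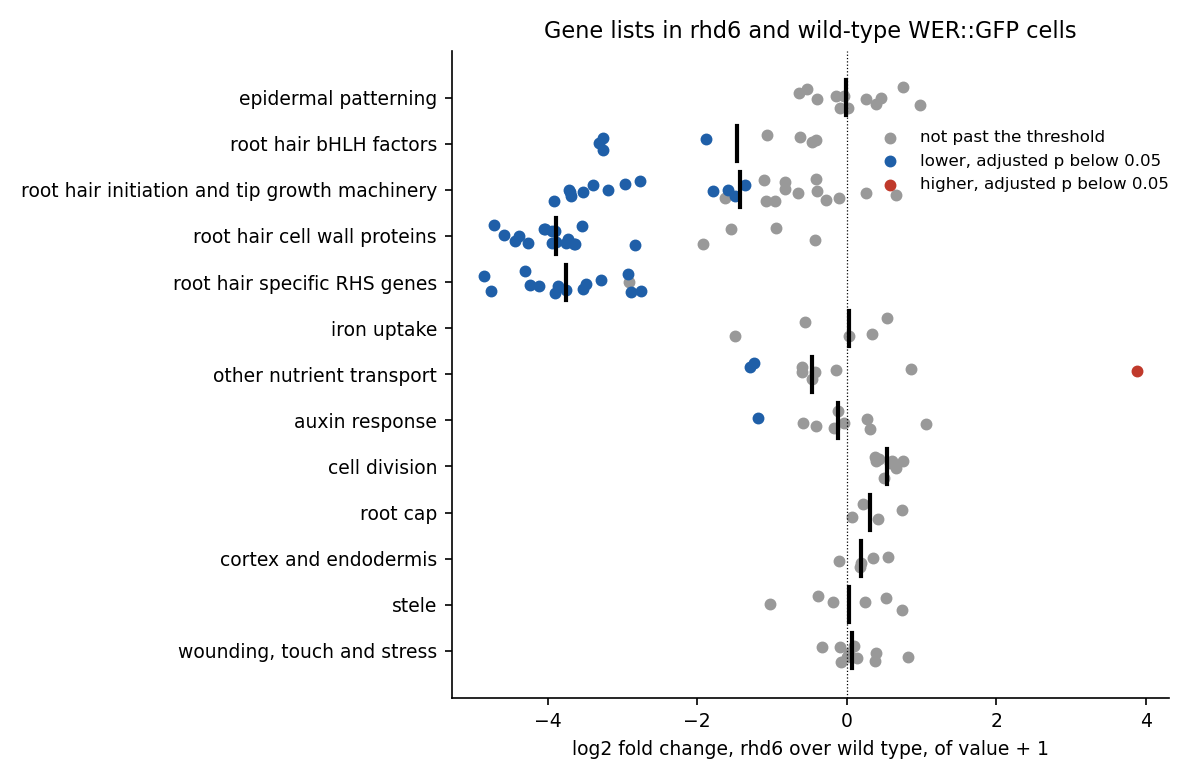
Log2 fold change of rhd6 over wild type on the value + 1 scale for each measured member of 13 gene lists. Each point is a gene and each black bar a list median. The medians of the wall protein and RHS lists lie at -3.88 and -3.75 and that of epidermal patterning at -0.01.

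None of the 12 measured epidermal patterning genes passed the test, 0 also over the list alone, 2 had an unadjusted p below 0.05, and edgeR called 0 and DESeq2 2. They were WER (0.46), GL2 (-0.09), CPC (-0.52), TRY (0.02), ETC1 (-0.63), GL3 (-0.03), EGL3 (0.98), TTG1 (-0.14), MYB23 (-0.40), SCM (0.75), TTG2 (0.40) and ZFP5 (0.25), given as log2 fold changes. GL2, which marks non-hair cells, was read at 66.4 ± 18.1 in wild type and 61.9 ± 14.0 in rhd6 (limma adjusted p = 0.882, n = 3 each), and the list's camera adjusted p was 0.705. EGL3 and SCM passed in DESeq2 (adjusted p = 0.0445 and 0.0322), and EGL3 passed in limma without library 10019 (adjusted p = 0.0371), with ranges over the alternatives of 0.0371 to 0.469 and 0.0322 to 0.389. In the authors' deposited test EGL3 had an FDR of 0.0332 and SCM 0.0882. GL3 was at 0.02 without the authors' scaling factors. The median of the list was -0.01 and its mean 0.09. ETC3 was not measured.

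Among other lists, cell division genes were higher as a set by camera at its preset correlation, with 0 of 8 members past the test in limma, edgeR or DESeq2 and 3 at an unadjusted p below 0.05, and transport and auxin genes were mixed. The cell division list had a median log2 fold change of 0.54 (camera adjusted p = 0.00235, and adjusted p = 0.619 with an estimated correlation), with CDKB2;2 at 0.75, CYCB1;2 at 0.65, AUR1 at 0.60 and CDKB2;1 at 0.51. Without the rhd6 library 10018 the median was 0.24 (camera adjusted p = 0.0179), and CYCB1;2 was read at 51.2 in that library, against 29.5 and 28.2 in the other rhd6 libraries. Of 9 nutrient transporters, the ammonium transporter AMT1;3 (-1.24) and the phosphate transporter PHT1;1 (-1.30) fell and PHT1;2 rose from 1 read to 842, while HAK5 was at 0.86. PHT1;1 and PHT1;2 are near-identical neighbours, so reads between them are uncertain. The list had a median of -0.47 and a mean of -0.00, and camera and fry gave it opposite directions (camera adjusted p = 0.523). Of 9 auxin genes, IAA5 fell by 1.18 and GH3.3 (1.06), IAA2 (-0.59) and PIN2 (0.32) did not pass (camera adjusted p = 0.689). The calls of AMT1;3 and IAA5 were lost when any 1 of the 6 libraries was left out, and also without the authors' scaling factors (adjusted p = 0.0614 and 0.0501). That of PHT1;1 (limma adjusted p = 0.0493) held in 4 of 14 alternatives, being lost when any 1 library but 10019 was left out, by edgeR (0.0588, and 0.0647 with median-of-ratios factors), with a pseudocount of 0.1 (0.0520), with median-of-ratios scaling (0.0549) and among genes with a mean of 5 or more (0.0635). Over 14 alternatives their adjusted p ran from 0.000754 to 0.154, from 0.000229 to 0.166 and from 0.00282 to 0.214. None of 5 measured iron uptake genes passed in limma or edgeR, with 1 at an unadjusted p below 0.05 and 1 passing in DESeq2 (BHLH39, adjusted p = 0.00128, over alternatives up to 0.343). They included BHLH39 (-1.50), FIT (-0.56), F6H1 (0.54) and FRO2 (0.34), and the list had a median of 0.03, a mean of -0.23 and a camera adjusted p of 0.650. BHLH39 had an FDR of 0.000421 in the authors' deposited test.

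No marker of other cells passed the test in limma. The 4 root cap genes, FEZ (0.75), SMB (0.42), BRN2 (0.22) and BRN1 (0.07), had 0 past the test in limma, edgeR or DESeq2, 1 at an unadjusted p below 0.05, 1 over the list alone (FEZ) and a camera adjusted p of 0.344. That p became 0.0104 without the rhd6 library 10018, the lowest over the alternatives, of which the highest, 0.854, was without the rhd6 library 10019. The median of the list was 0.32, and -0.20 without library 10019, where BRN2 and BRN1 were read at 179 and 149 normalized CPM, against 23.1 and 19.1 in library 10018 and 75.5 and 79.8 in library 9519, so the list has no direction that holds over the libraries. The cortex and endodermis list (SCR 0.55, CASP1 0.35, MYB36 0.19) and the stele list (PHB 0.75, COBL4 -1.03, CESA7 0.53, AHK4 -0.38) had camera adjusted p of 0.648 and 0.689, with 0 members past the test in limma and edgeR. At an unadjusted p below 0.05 were 0 and 1 members, PHB was higher over the list alone, and DESeq2 called PHB and COBL4. The authors' deposited test gave COBL4 an FDR of 0.0262 and PHB 0.114. The median of the cortex and endodermis list was 0.19, and -0.41 without the rhd6 library 10019, so its direction does not hold over the libraries either. In library 10019 CASP1 and MYB36 were read at 14.3 and 5.08, against 2.31 and 1.10 in library 10018 and 2.88 and 0.222 in library 9519. Wounding, touch and stress genes (TCH4 0.83, ZAT10 0.40, WRKY40 -0.34, RD29A 0.38) had a camera adjusted p of 0.689 and 0 of 10 past the test in limma, edgeR or DESeq2 and 0 at an unadjusted p below 0.05. No member of the photosynthesis list was measured.

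The second comparison asks whether genes lower in rhd6 are found in hair cells sorted in the same way by another reporter, and in hairs isolated by sieving. Both hair tables are of wild-type plants, and a gene can be called lowered only where wild type reads it, so the groups were also matched on wild-type level. Genes lowered in rhd6 were detected more often than others in both Arabidopsis hair tables, also at matched levels, where the difference in sieved hairs was small. In sorted COBL9::GFP cells 551 of 573 lowered genes (96.2%) reached a mean FPKM of 1, against 14550 of 17002 other tested genes (85.6%), an odds ratio of 4.22 (two-sided Fisher's exact test across genes, p = 2.44e-16), and of 4.09 within 20 classes of wild-type level (Mantel-Haenszel p = 1.08e-09). In sieved hairs 474 lowered genes (82.7%) were listed, against 75.6% of the others (odds ratio 1.55, Fisher's exact p = 5.66e-05, and 1.36 within classes, Mantel-Haenszel p = 0.0129), and 472 were found in both. The unmatched test passed 0.05 in 62.5% of random sets with the wild-type levels of the lowered genes and the matched test in 7%, so the unmatched p-values carry little weight. The matched p was 0.0472 in sieved hairs without library 1, in a range of 0.00193 to 0.0472, and 0.0925 in COBL9::GFP cells at an FPKM of 0.1, in a range of 1.92e-28 to 0.0925. At an FPKM of 0.1 all 573 lowered genes were detected, against 569 expected, so that level leaves little room for a difference. The matched test was added after the data were seen. The median FPKM in COBL9::GFP cells was 19.2 for lowered, 0.523 for raised and 8.18 for other genes, and their median normalized CPM in wild-type WER::GFP cells was 21.0, 1.15 and 18.2, so the raised genes were low in wild type in both and were not tested. Genes are not independent replicates, so these p-values describe the lists.

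In the root hair tables, levels were described without a test, since each table was normalized separately. Hair wall genes were read at high levels in COBL9::GFP cells. The peroxidase PRX57 was at 2017 ± 962 FPKM, PRP3 at 1269 ± 635 and EXPA7 at 405 ± 282 (SD, n = 3), and the wall list's median of 405 lay at percentile 100 among 10000 random lists of its size. RHD6 was at 61.0 ± 56.2, RSL4 at 120 ± 78.4 and LRL3 at 163 ± 118, and the bHLH list's median of 44.6 lay at percentile 99.9. Tip growth (median 114), RHS (54.9), auxin (80.0) and stress genes (110) lay at percentile 100, and nutrient transport (19.6) at 99.4. Epidermal patterning (4.26) lay at 88.2, photosynthesis (6.48) at 78.3, cell division (3.36) at 74.96, cortex and endodermis (1.39) at 60.1, stele (0.483) at 38.9 and iron uptake (0.165) at 17.1. The random lists were drawn from all 33550 genes, whose median was 0.808 FPKM, so a high percentile can mean only that a list is expressed in roots. Over the 14919 genes that the sieved table lists, wall genes stayed at 100 in COBL9::GFP cells. There the listed members of cell division lay at 20.2 and those of cortex and endodermis at 9.26. Root cap genes (69.1) lay at 99.2, with list medians of 8.18, 130 and 68.4 in the 3 libraries, while the wall list's medians were 529, 232 and 459. The highest genes were AT1G52070, a mannose-binding lectin (792, 14470 and 8325 FPKM in the 3 libraries), and AT1G07590 and the metallothionein gene MT1A (7265 ± 2786 for each). Next came AT5G54370 (6898 ± 5818), the beta-glucosidase gene PYK10 (3912 ± 959), the arabinogalactan protein gene AGP2 (3677 ± 163) and AT1G52060 (3525 ± 3325). The chitinase family gene AT2G43610 (3341 ± 3073), AT5G26260 (3167 ± 834) and the glutathione transferase gene GSTU19 (3071 ± 885) followed. AT5G54370, AT1G52060 and AT2G43610 were at 1049, 284 and 285 in the first library and 12685, 6928 and 6430 in the second. AT1G07590 and MT1A carry the same values in every library, so their reads are not told apart.

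Sieved Arabidopsis hairs were led by AT1G07590 and MT1A (37089 ± 4500 FPKM for each, n = 3), PYK10 (8470 ± 1494), MT1C (6779 ± 1526) and the extensin gene EXT3 (4544 ± 3448). AT1G54410 (3859), the chloroplast gene ATCG00390 (39.3, 6728 and 2113 in the 3 libraries), PBP1 (2873), RCI2A (2658) and the defensin-like gene LCR67 (7795, 3.29 and 2.66) completed the 10 highest. Hair wall genes had a median of 475 FPKM (percentile 100), and it was 962, 149 and 275 in libraries 1, 2 and 3. Nutrient transport (158) lay at percentile 100, tip growth (71.9) at 99.99, RHS genes (85.1) at 99.95, stress (44.1) at 92.6, iron uptake (50.7) and bHLH factors (49.1) both at 91.6, auxin (46.7) at 85.0, patterning (26.4) at 62.3, photosynthesis (37.3) at 62.1, stele (14.9) at 30.0, cortex and endodermis (11.3) at 22.3 and cell division (4.95) at 1.69. These values rest on the listed members only, which were 3 of 13 for patterning, 4 of 10 for auxin, 5 of 12 for iron uptake, 5 of 11 for stele, 3 of 8 for cell division, 3 of 7 for cortex and endodermis, 2 of 3 for photosynthesis, 6 of 8 for bHLH factors, 8 of 11 for nutrient transport, 8 of 10 for stress, 20 of 21 for wall genes, 15 of 15 for RHS and 26 of 26 for tip growth, while the COBL9::GFP values use all members, so the percentiles of the 2 tables rest on different members. None of the 4 root cap genes was listed. RHD6 was listed at 18.4, 39.4 and 5.30. Libraries 1, 2 and 3 listed 1683, 1206 and 77 genes at 0.

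**Figure D4:**
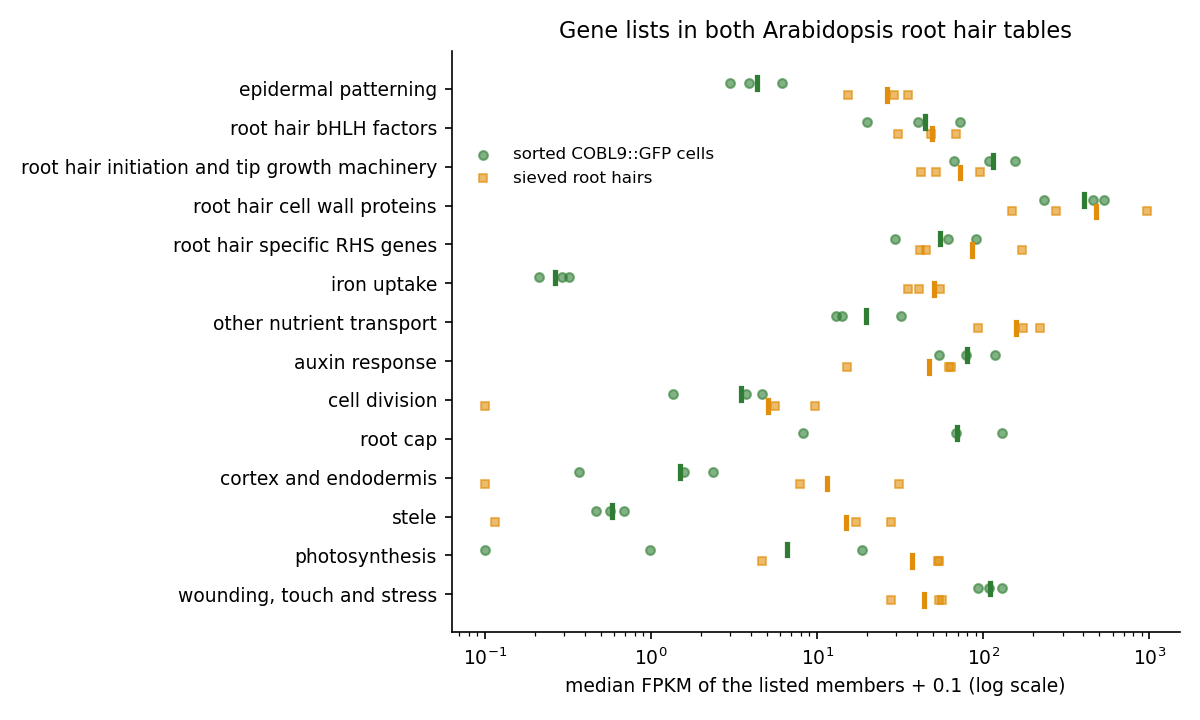
Median FPKM plus 0.1 (log axis) of the listed members of each gene list in both Arabidopsis root hair tables. Points are the 3 libraries and bars the median of the means, and the sieved table lists only genes with a mean of 3 or more. Wall protein medians are 405 in sorted and 475 in sieved material.

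The number of genes at a mean FPKM of 1 or more was 16164 of 33550 in COBL9::GFP cells and 17733 of 58047 in EXPA30::GFP rice cells. The sieved tables list only genes with a mean FPKM of 3 or more, so their sizes are not comparable with these. They held 14919 genes in Arabidopsis, 12229 in rice, 12622 in cucumber, 16652 in soybean, 12970 in tomato and 14471 in maize. The lowest Pearson r between replicates, across genes on log2(FPKM + 1), was 0.943 for COBL9::GFP, 0.967 for EXPA30::GFP, 0.372 for sieved Arabidopsis, 0.645 for soybean, and 0.891 to 0.914 for the other 4 species. The r of sorted cells runs over all genes, many of them listed at 0, and that of sieved hairs over the genes they list. Sorted and sieved values of r are therefore not comparable either. The highest genes, by identifier only, were LOC_Os08g10480 (5580 ± 1164 FPKM) and LOC_Os04g44790 (5120 ± 1294) in EXPA30::GFP cells. In sieved hairs they were LOC_Os03g17870 (12149 ± 2835) and LOC_Os05g15770 (11660 ± 2284) in rice, and Solyc10g074860.1 (24253 ± 3325) and Solyc04g071100.1 (10965 ± 1014) in tomato. The 2 highest cucumber genes were at 18139 ± 9489 and 11841 ± 1111. Those of maize were GRMZM2G099496 (16832 ± 4707) and GRMZM2G023132 (7854 ± 1312), and those of soybean GLYMA12G06111 (46180 ± 33465) and GLYMA10G35080 (12573 ± 5335).

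Sorted and sieved hair cells shared many of their highest genes. In Arabidopsis 223 of the 500 highest genes (44.6%) were the same in both tables, against 7.45 by chance over the 33550 genes of the sorted table and 15.4 over the 14919 that the sieved table lists, and the Spearman correlation across those 14919 genes was 0.578. In rice 168 (33.6%) were shared, against 4.31 by chance over 58047 genes and 18.8 over the 12229 listed, and the correlation across the 12229 genes was 0.530. No test was made, since genes are not independent replicates and the isolation and the library kit differ together. No table of other cells was compared, so genes shared by hairs are not told apart from genes high in many cells. Over the genes that the sieved table lists, the stele list lay at percentile 0.460 in COBL9::GFP cells and 30.0 in sieved hairs, cortex and endodermis at 9.26 and 22.3, and iron uptake at 87.1 and 91.6. Cell division lay at 20.2 and 1.69 and auxin genes at 99.87 and 85.0. These lists hold only members with a mean FPKM of 3 or more in sieved hairs, while no COBL9::GFP level was asked for. That can favour a higher percentile in sieved hairs, so higher percentiles there are not told apart from this choice of members. The median of the stele list in sieved libraries 1, 2 and 3 was 0.0157, 27.6 and 17.2. Without sieved library 1, 2 or 3 the Arabidopsis correlation was 0.508, 0.636 and 0.555.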

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

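The edgeR and DESeq2 fits on recovered reads, the other scalings the list tests with another pseudocount or scaling and the detection test matched on level were chosen after the data were seen, and all other alternatives were planned. The counts of total, raised and lowered genes in rhd6 were 431, 72 and 359 among genes with a mean of 5 or more, where fewer genes were tested, 1352, 376 and 976 by DESeq2, for which the cause was not tested, and 346, 72 and 274 at an adjusted p of 0.01. They ran from 222 to 784, from 42 to 122 and from 165 to 683 when 1 library was left out. No filter (727), a pseudocount of 0.1 (705), edgeR (665, of which 648 are among the 724), edgeR with median-of-ratios factors (649), values without the authors' scaling factors (764), median-of-ratios scaling (715) and changes of at least 2-fold (690) stayed within 1.5 times 724. Leaving out a library reduces the residual degrees of freedom. It also drops genes read only in the genotype that loses a library, as the filter still asked for 3 libraries at 1 or more. The lists called numbered 0 with an estimated correlation, 4 by fry, and 5 to 6 when 1 library was left out. No named gene past the threshold reversed, signs of named genes not past it changed 21 times over all settings, and 5 called genes lost and 6 uncalled genes gained a call under some alternative. All odds ratios for detection of lowered genes stayed above 1. The unmatched ones also stayed past the threshold, in a test that passed it in 62.5% of random sets of matched level, and of the matched ones that of COBL9::GFP cells at an FPKM of 0.1 did not. At that level all 573 lowered genes were detected, against 569 expected.

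The count of genes in EXPA30::GFP cells at a mean FPKM of 5 was 11263. With a pseudocount of 0.1 the lowest replicate r was 0.220 for sieved Arabidopsis, 0.856 for rice, 0.885 for cucumber, 0.551 for soybean, 0.864 for tomato and 0.872 for maize, and the cause was not tested. The 100 and 1000 highest genes shared 36% and 49.2% in Arabidopsis and 23% and 37.7% in rice. When 1 library was left out, the Arabidopsis correlation ran from 0.508 to 0.636 and the share of the 500 highest genes from 38.2% to 46.6%, and those of rice from 0.507 to 0.542 and from 32.4% to 34.2%. An FPKM level of 0.1 gives nothing in the sieved tables, which start at a mean of 3, and a test on FPKM beside counts was not run, as the rhd6 table holds none. No paired analysis was possible because no label ties the library numbers of the WER::GFP columns to replicate numbers. Depth limits genes near 1 normalized CPM, and simulated changes of 1 on the log2 scale were called for 10.6% of genes.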

Other observations

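The tests of gene families, of gene positions, of library 10019 and of sieved libraries 1 and 2 were chosen after the result was seen, and the count of other splits was set before. Genes outside the lists that fell in rhd6 are given here as single genes and not as a tested set. The ROP activator gene ROPGEF10 had a log2 fold change of -3.37, ROPGEF12 -2.96, ROPGEF4 -2.92 and ROPGEF11 -1.94, and the ROP effectors RIC1 and RIC10 -2.69 and -2.22. The exocyst genes EXO70C1 and EXO70C2 were at -2.69 and -2.20, the actin depolymerizing factors ADF8 and ADF11 at -3.49 and -3.32, and the peroxidase gene AT3G49960 went from 284 ± 63.1 to 12.1 ± 8.18 normalized CPM (n = 3 each, limma adjusted p = 0.00226). The metal transporter IRT2 (-2.79) and the sulfate transporter SULTR1;1 (-2.54) fell. The limma adjusted p of these genes ran from 0.00131 for EXO70C1 to 0.0460 for ROPGEF4, and all were named after their values were seen. ROP2 and ROP4 themselves did not pass (ROP2 limma adjusted p = 0.181, ROP4 0.180).

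By product name, 7 of 167 families were over-represented among lowered genes and 2 among raised genes (one-sided Fisher's exact test across genes). Disease resistance genes of the TIR-NBS-LRR class held 10 lowered genes of 41, against 1.34 expected (adjusted p = 9.44e-05), among them AT4G16920 (-3.06) and AT5G46520 (-2.54), examples chosen after their values were seen. The C1 domain family held 14 of 98 (adjusted p = 0.000287), proline-rich extensin-like genes 5 of 10 (adjusted p = 0.000443), DUF247 proteins 5 of 15 (adjusted p = 0.00346), uncharacterized proteins 49 of 867 (adjusted p = 0.00430), and CC-NBS-LRR and proline-rich proteins 4 of 15 each (adjusted p = 0.0273). Among raised genes, S-locus lectin kinases held 4 of 16 (adjusted p = 0.00147), namely AT1G61370 (1.73), AT1G61390 (1.34), AT1G61430 (1.76) and AT1G61440 (1.92), and mannose-binding lectins 3 of 18 (adjusted p = 0.0385). The test counts neighbouring genes as independent, while both raised and lowered genes lie closer together than chance and members of several of these families are neighbours, such as the 4 kinase genes, and AT5G46510 beside AT5G46520 in the TIR-NBS-LRR class, so families are not told apart from position. Members of such families can share reads.

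The 151 genes raised in rhd6 lay close together. They formed 159 pairs 4 to 50 tested genes apart, against a median of 60, a 95% interval up to 76 and a highest of 96 in 10000 random sets. In sets of the same size from the lowered genes that interval reached 86, which argues against genes spread over the genome like the lowered ones. A lowered neighbouring copy was found for 3.31% of raised genes. A copy counted only where it had the same product name and was itself called lower, so reads moved between neighbouring copies are not decided. Of the raised genes, 92.7% lay on chromosomes 1, 2 and 5 (64.6% of tested genes) and 36 lay within 500 tested genes of RHD6, against 8.60 expected, so a candidate explanation is that the rhd6 line carries DNA of another accession around RHD6 and elsewhere, although its label is Columbia. A first form of the test, on 57 genes read in 1 genotype only, gave 18 pairs (interval up to 15), 3 for genes read in rhd6 only (2.02) and 4 for those read in wild type only (9), and it was replaced after these were seen. The 573 lowered genes were also closer than chance, with 981 pairs against a median of 869 and 49 genes near RHD6 against 32.6 expected. DNA of another accession may thus bear on falls near RHD6 too. The pair counts show the clustering only, and neither such DNA itself nor other reasons for clustering were tested.

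Hair genes were retained more in the rhd6 library 10019 than in the other rhd6 libraries, and 45 of the 48 lowered hair genes were highest there. Mixed-in wild-type RNA would put a floor under every gene, but 18 of 8324 genes with a wild-type mean of 20 or more lay below 4.17% of wild type, under the 16.7% median of hair genes, which argues against it. In normalized CPM, RHD6 was at 0.750 times its level in library 10018 (95% interval 0.368 to 1.48, from 15 and 25 reads), while the median hair gene was 6.67 times higher (quartiles 5.09 and 8.66). The first argues against residual RHD6 transcript, while the second restates the pattern and decides nothing about a larger share of root cap cells. Some markers of other cells were also higher than in library 10018, BRN2 at 179 against 23.1 and CASP1 at 14.3 against 2.31, so a difference in the cells sorted is left open, root cap cells included, and no biological explanation but residual RHD6 transcript was tested, since no label separates the 3 libraries.

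Sieved Arabidopsis library 1 listed 1683 genes at 0, library 2 1206 and library 3 77. Among 14341 genes split into 3 classes by COBL9::GFP level, 22.9% of the lowest and 4.12% of the highest class were at 0. Matched on level in the other libraries, the Mantel-Haenszel odds ratio was 7.89, while it was 1.22 for zeros of library 2, whose cause was not tested. The libraries matched on are noisy (r between replicates 0.372 to 0.651), so COBL9::GFP level can still stand for level in sieved hairs. Dropout by level alone in library 1 is therefore not decided. The highest ratio of library 1 to the others among the medians of the cortex and endodermis and stele lists (3 and 5 genes) was 0.000700, while hair wall genes had medians of 962 and 208. The low medians partly restate the zeros they would explain. That library 1 holds less RNA of cells other than hairs is therefore a candidate only. The prediction for other cells was reworded after it was seen that no root cap gene is listed, and no biological explanation was tested.

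Of the 10 splits of the 6 WER::GFP libraries into 3 and 3, 1, the real one, gave 724 calls, and the highest of the others gave 0. The 10 splits are too few for a share under 0.05.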
